A study of Drosophila melanogaster with 6 samples.

How the data were processed

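Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on wandering larvae of the third instar of the fruit fly Drosophila melanogaster, from the y; cn bw sp strain that carries yellow, cinnabar, brown and speck alleles. The labels describe 3 ChIP libraries made with a mouse monoclonal antibody and 3 libraries of input DNA, which is sonicated chromatin that was not immunoprecipitated. Each library carries a replicate number, and no label says whether the replicates came from separate collections of larvae, so they may be technical. The series title names TCF, the transcription factor also called Pangolin, whereas the antibody label and the design text name tango, the common bHLH-PAS dimerization partner of Trachealess, Single-minded and Spineless. Which protein was precipitated was not settled from the data, and the ChIP libraries are called anti-tango after the antibody label.

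The authors deposited 1 list of peaks for all 6 libraries, with the sequence, the positions of the outermost bases and a score for every peak. Per the file headers, the coordinates are those of FlyBase release 5 and the peaks come from MACS. Per the submitters' processing notes, CASAVA 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the BDGP5 build were used, without a role or order for each tool. How replicates were combined, how reads mapping to several places were treated and which threshold was applied are not given in the sources used here. The deposited score of each peak is the authors' own value, with 2 decimals and a range of 6.37 to 1518.05. Its scale is not given (a log-transformed p or q, with or without a factor of 10), so it was compared only within this list. Ranks do not depend on that scale. A factor of 10 would change differences in median score, but not Pearson's r or relative interquartile ranges. A p in place of a q could change each of these values, so they hold for the score as deposited. There is no value per library. Read depth is therefore unknown, no replicate error can be given, and the ChIP replicates could not be set against the input replicates.

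Peaks were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The 15 sequences of the list were grouped as the 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X), the 6 heterochromatin scaffolds named Het, the unplaced collections U and Uextra, and the mitochondrial genome. U and Uextra are joined unplaced scaffolds, so distances along them have no chromosomal meaning. Because no genome of release 5 was used here, the length of a sequence was taken as its span from the outermost base of the first peak to that of the last. This understates true lengths, most of all on short sequences with few peaks.

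The number of peak centres per arm was compared with the arm's share of the summed spans by an exact two-sided binomial test, with Benjamini-Hochberg adjustment over the 6 arms. Clustering was tested against 1000 random placements of the same peaks within their arms without overlap, using the share of peaks with a neighbouring centre within 5 kb and the median distance between neighbouring centres. Width and score were compared by Pearson's r and Spearman's rho, with 100000 permutations. Peaks of 1 list are not biological replicates, and neighbouring peaks are not independent, so these p-values describe this list and not the spread between larvae. Intervals on shares are 95% Wilson intervals and those on densities are 95% exact intervals. They cover counting error only.

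These tests, the alternatives first listed and the rule for named peaks (the 10 peaks with the highest score) were fixed before the data were examined. Comparisons added afterwards are the score of Uextra against the arms (100000 permutations of the difference in medians), the share of peaks in the 10% of each large arm nearest the centromere (10000 circular shifts within arms, two-sided) and recurrent peak widths (10000 resamples of widths of at least 3 kb, smoothed by 10%, scanned with a 200 bp window). The limits behind these comparisons (focal peaks, peaks of at least 4 kb, the 9.0 to 9.2 kb and 5.7 to 6.1 kb groups) were set after widths and scores had been looked at. The largest gap counted between a peak and its neighbour was first set to 300 bp and was raised to 400 bp after a neighbour at 308 bp had been seen, and counts at both limits are given. The centromere side was taken as the high-coordinate end of 2L, 3L and X and the low-coordinate end of 2R and 3R. The tests were tested on simulated data. With 1980 peaks spread evenly over the arms, clustering was called in 3% of 100 data sets, a centromere-side excess in 6% and at least 1 uneven arm in 4%. Each was called in 100% of data sets with a planted effect (20 data sets for clustering, 100 for the others), which was 20% of peaks moved next to another, 10% moved to the centromere side or 100 peaks moved from 3R to 2L. Recurrent widths were called in 4% of smooth data sets of 120 peaks and in 100% of those with 40 peaks of a shared width. With no effect, the tests of medians (600 peaks) and of correlations (300 peaks) called 5% and 4%, and each called 100% when a score was doubled or a slope of 0.5 was planted. No simulated data set without an effect held grouped peaks. The rates of false calls for the arm, centromere-side, median and correlation tests therefore do not cover peaks that lie in groups. The simulated runs also used fewer placements, shifts and resamples than the runs on the data.

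Analyses of promoters, gene features, binding motifs (including those of Tango dimers and TCF) and gene lists had been fixed as well. They need the release 5 sequence and annotation. The gene table at hand is of release 6 and holds other coordinates, and coordinates were not converted between releases. These analyses were therefore not run, no peak was given a gene name, and peaks are named by position. Alternatives that were run kept only peaks at or above the median score of the list (57.68), the top 25% by score (105.74 or above) or the 5 large arms, merged peaks with centres within 500 bp, replaced centres by covered bases, and used neighbour distances of 2 and 10 kb. Alternatives chosen after seeing the data merged peaks within 10 kb (a merged region takes its highest score), used peaks at or above the median score of the arms, peaks of at most 1 kb, or focal peaks (at most 1 kb wide with a score of at least 100), left out the centromere-side 10% or each arm in turn, and, for width and score, took the arms, Uextra, U and the heterochromatin scaffolds singly or left out the 2 widest peaks.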

Results

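The anti-tango ChIP with input DNA in larvae of the third instar asked where in the genome the precipitated DNA was enriched. The study has 3 ChIP and 3 input libraries and 1 list of peaks, with 13745 regions on 15 sequences. Peaks had a median width of 575 bp (interquartile range 387 to 742 bp) and were up to 26370 bp wide. Their median score was 57.7 (interquartile range 21.3 to 106), on the scale the authors' peak caller gave. In total they covered 9938 kb. The library totals behind these values are unknown, and there is no replicate value for any peak.

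Most peaks lay outside the assembled chromosome arms. Uextra, a collection of small unplaced scaffolds of this genome release, held 10412 peaks, or 75.8% of the list (95% Wilson interval 75.03 to 76.46%). The 6 arms held 1980 peaks (14.4%, 13.8 to 15.0%), the other unplaced collection U held 794 (5.78%, 5.40 to 6.18%), and the 6 heterochromatin scaffolds held 540 (3.93%, 3.62 to 4.27%). Relative to the spans covered by the list, there were 359 peaks per Mb on Uextra, 79.5 on U, 60.7 on the heterochromatin scaffolds and 16.5 on the arms. Peaks covered 23.2% of the span of Uextra, 7.89% of U, 3.93% of the heterochromatin scaffolds and 1.73% of the arms. Among the heterochromatin scaffolds, 2LHet was densest at 115 peaks per Mb (41 peaks), followed by 3LHet at 67.7 (170 peaks), 2RHet at 58.5 (192 peaks), 3RHet at 51.9 (125 peaks) and XHet at 49.1 (10 peaks). YHet, from the Y chromosome, had 2 peaks.

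Scores differed between these sequence groups as well. The median score was 78.8 on Uextra (interquartile range 29.7 to 110) and 20.1 on the arms (13.6 to 39.0), a difference of 58.8 that was larger than in any of 100000 permutations of the peaks (two-sided p = 1e-05, the smallest they can give). U was intermediate at 36.3, whereas the heterochromatin scaffolds, at 17.0, lay below the arms (no test was run for these groups). A score of at least 100 was reached by 34.5% of peaks on Uextra (33.6 to 35.4%), 30.9% on U (27.7 to 34.2%), 8.18% on the arms (7.05 to 9.47%) and 2.96% on the heterochromatin scaffolds (1.83 to 4.76%). The comparison of Uextra with the arms was chosen after the counts had been seen.

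**Figure D1:**
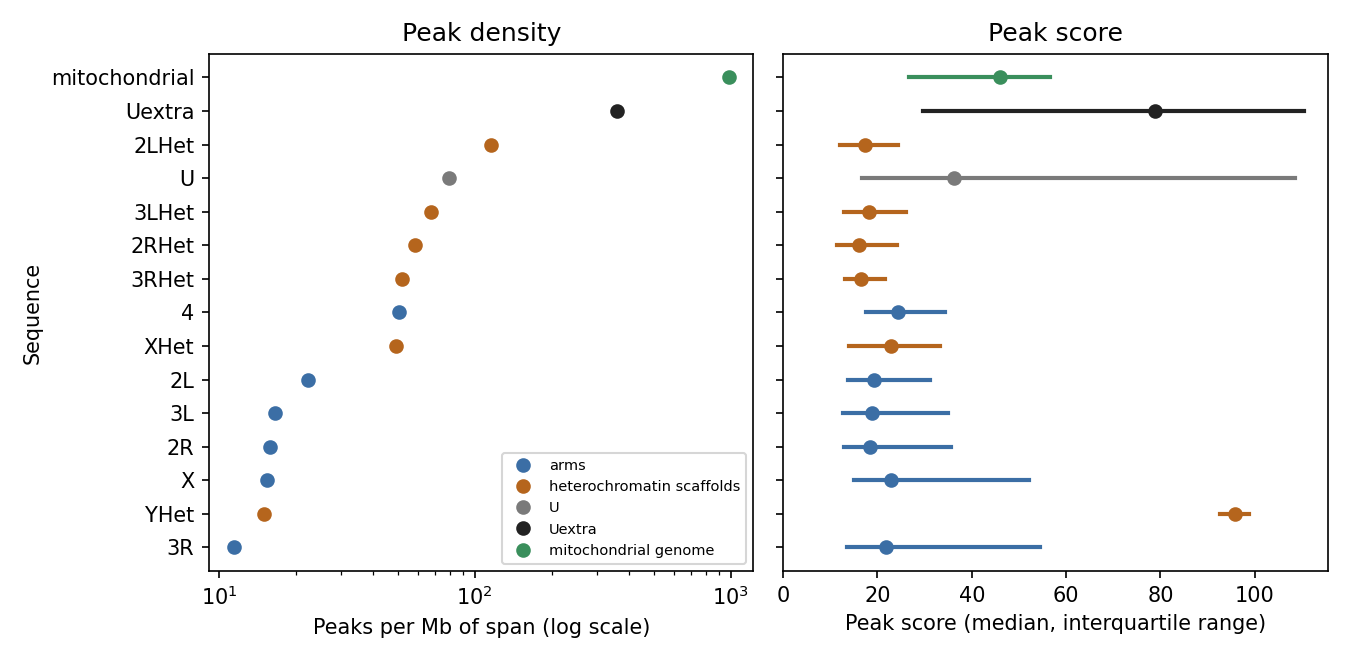
Peak density in peaks per Mb of span on a log axis (left) and peak score as median with interquartile range (right) for the 15 sequences of the list, coloured by sequence group. Uextra stands above every arm in both panels, with 359 peaks per Mb and a median score of 78.8, and the point for YHet rests on 2 peaks.

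The 10 highest-scoring peaks were split between 2 places on the arms and 8 on unplaced sequence. The strongest peak of the list lay on X at 1521939 to 1529579 (release 5), was 7641 bp wide and had a score of 1518.05. The third was on 2L at 20176665 to 20198135, spanned 21471 bp and scored 1509. Between them stood a peak of 1740 bp on Uextra at 597375 to 599114, with a score of 1517. A further 6 of the 10 were on Uextra, between 896 and 1742 bp wide and with scores of 1375 to 1430. Those ranked 5 and 6, at 7760878 to 7762619 and 16676453 to 16678068, had the same score of 1407.82. The tenth, on U at 9647772 to 9648465, scored 1337 over 694 bp. Which genes or repeats lie at these places was not determined, because no annotation of release 5 was used.

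Within the assembled genome, peaks were unevenly spread over the arms. Chromosome 4, the small and largely heterochromatic dot chromosome, had 62 peaks, 3.07 times the even expectation (95% exact interval 2.36 to 3.91, adjusted p = 1.35e-13). Arm 2L had 514 peaks, 1.35 times expectation (1.25 to 1.46, exact adjusted p = 2.99e-13), and 3R had 318, 0.69 times expectation (0.62 to 0.77, adjusted p = 3.08e-14). The other arms did not pass. By the exact test, 2R had 332 peaks at 0.96 times (0.86 to 1.05, adjusted p = 0.470), 3L had 408 at 1.01 times (0.92 to 1.10, adjusted p = 0.867) and X had 346 at 0.94 times (0.85 to 1.03, adjusted p = 0.291). All are exact binomial tests, two-sided and adjusted over the 6 arms, and because peaks lie in groups they overstate the certainty. By covered bases in place of peak centres, chromosome 4 was at 1.55 times expectation. The excess on 2L ended when peaks within 10 kb were merged (1.06 times, exact binomial adjusted p = 0.490). None of the 6 arms passed at or above the median score of the list, where chromosome 4 kept 1 peak and the arms together kept 328.

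Over the 5 large arms together, peaks were concentrated on the centromere side. Of 1918 peaks, 489 (25.5%) lay in the centromere-side 10% of the span, against a mean of 9.99% over 10000 circular shifts (two-sided p = 0.0004, n = 1918 peaks). The share was 41.2% on 2L (212 of 514 peaks), 28.4% on 3L (116 of 408), 22.9% on 2R (76 of 332), 16.5% on X (57 of 346) and 8.81% on 3R (28 of 318). With all peaks, no single arm passed after adjustment over the 5 arms, with permutation adjusted p between 0.171 and 0.788. Among peaks at or above the median score of the arms, 2L passed, with 42.4% (103 of 243 peaks, adjusted p = 0.026 by circular-shift permutation). No arm passed in any other setting. By the same permutation, 2L stood at 20.3% after merging within 10 kb (adjusted p = 0.07). At or above the list median it stood at 17.4% (adjusted p = 0.415 by permutation). The fullest 1 Mb bin was 21 to 22 Mb of 2L, with 132 peaks or 25.7% of that arm, where the median bin held 12. It was followed by 22 to 23 Mb of 2L with 62 peaks, 23 to 24 Mb of 3L with 61 and the first Mb of 2R with 52. Away from the centromeres, 15 to 16 Mb of 2R held 42 peaks with a median score of 14.4. Without 2L the share on the centromere side was 19.7% (p = 0.0068, n = 1404 peaks). Without that 10% of each large arm, 2L stood at 1.06 times expectation (exact adjusted p = 0.533), 3R at 0.84 times (adjusted p = 0.00175) and chromosome 4 at 3.67 times (adjusted p = 8.01e-17). This comparison was also chosen after the counts had been seen, and it did not hold for peaks at or above the median score of the list, of which 12.8% were in the centromere-side 10% (p = 0.1782, n = 327 peaks).

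**Figure D2:**
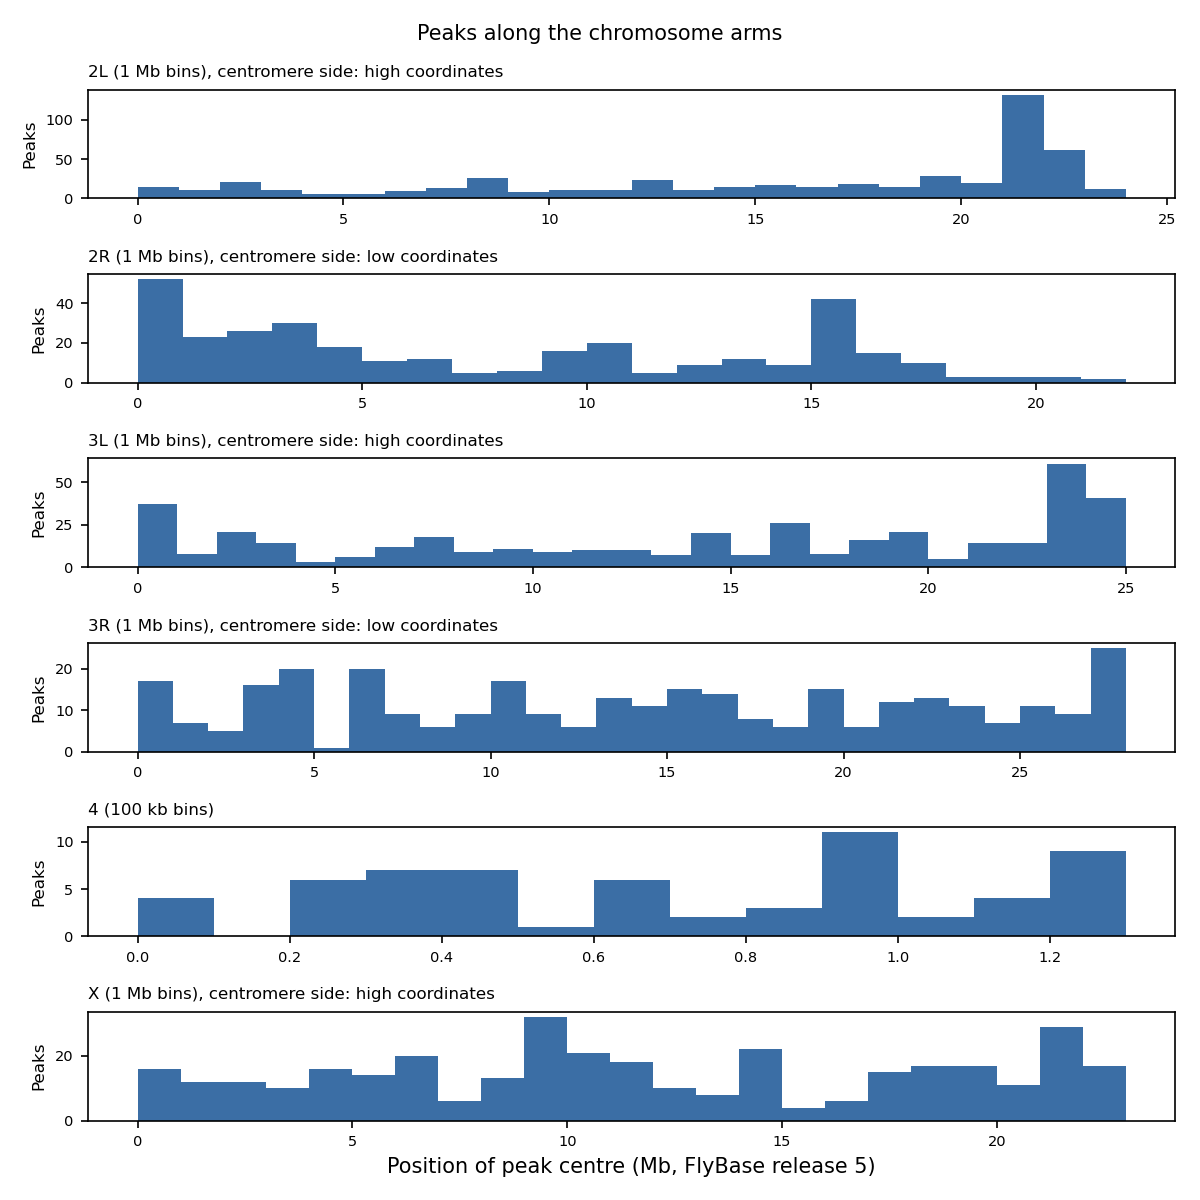
Number of peak centres per 1 Mb bin along 2L, 2R, 3L, 3R and X, and per 100 kb bin along chromosome 4, against position in Mb of release 5. The bars are tallest at the high-coordinate end of 2L, where 21 to 22 Mb held 132 peaks, and the vertical scale differs between arms.

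Peaks on the arms occurred in groups. The median distance between neighbouring centres was 7673 bp, against 40478 bp on average when the same 1980 peaks were placed at random (two-sided p = 0.002, the smallest that 1000 placements can give, n = 1980 peaks). A neighbour within 5 kb was found for 64.0% of peaks, against 13.5% on average and at most 17.0% over the random placements (p = 0.002, n = 1980 peaks). Outside the centromere-side 10% of the large arms, 59.2% of 1491 peaks still had such a neighbour, against 11.1% at random (p = 0.002, n = 1491 peaks). A split of broad regions into adjacent peaks could also produce such groups. Another peak lay within a gap of 400 bp for 951 of the 1980 peaks (48.0%). Merging centres within 500 bp left 1891 peaks, but centres of adjacent wide peaks lie further apart. How much of the grouping comes from splitting was therefore not settled. Of the 154 arm peaks in the top 25% of the list, 19.5% had another of them within 5 kb, against 0.96% at random (p = 0.002, n = 154 peaks). This share includes both members of 7 couples, each a wide peak with a narrow neighbour, described under Other observations. The share without these couples was not computed, so it is not known how far it holds for other strong peaks. The median spacing of the 154 peaks did not differ detectably from random (p = 0.6693, n = 154 peaks). None of the 130 focal peaks, at most 1 kb wide with a score of at least 100, had another focal peak within 5 kb, where 0.96% was the mean at random (p = 1, n = 130 peaks).

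Wider peaks had higher scores. Across all 13745 peaks, Spearman's rho between width and score was 0.68 and Pearson's r was 0.23 (both permutation p = 1e-05 and the same after adjustment over 8 such relations). Pearson's r was 0.42 without the widest and narrowest 5% of peaks and 0.60 on a log scale. The groups of sequences were taken singly only after the data had been seen. Within them rho was positive as well, with a rho of 0.75 on Uextra (10412 peaks), 0.79 on U (794), 0.50 on the arms (1980) and 0.48 on the heterochromatin scaffolds (540). These are correlations across peaks of 1 list, which are not independent replicates. Width and score also come from the same peak calling, so they are not separate measurements. The permutation p tests only against no relation between them.

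Narrow peaks with high scores and wide peaks with moderate ones were both present on the arms. Focal peaks numbered 130, with 24 on 2L, 20 on 2R, 26 on 3L, 30 on 3R, 29 on X and 1 on chromosome 4, and no arm passed the exact binomial test against an even spread (each adjusted p = 1). Their median width was 596 bp (interquartile range 531 to 716 bp). The strongest focal peaks were at 15527722 to 15528507 on 3L (score 736), 18178744 to 18179361 on 3L (652), 480792 to 481353 on 2L (600.01), 2031119 to 2031681 on X (594) and 10194981 to 10195738 on 2R (579.6). Peaks of at least 4 kb numbered 115 and together made up 47.4% of all bases covered on the arms, and 104 of them scored between 40 and 80. Both groups were chosen after the data had been seen.

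**Figure D3:**
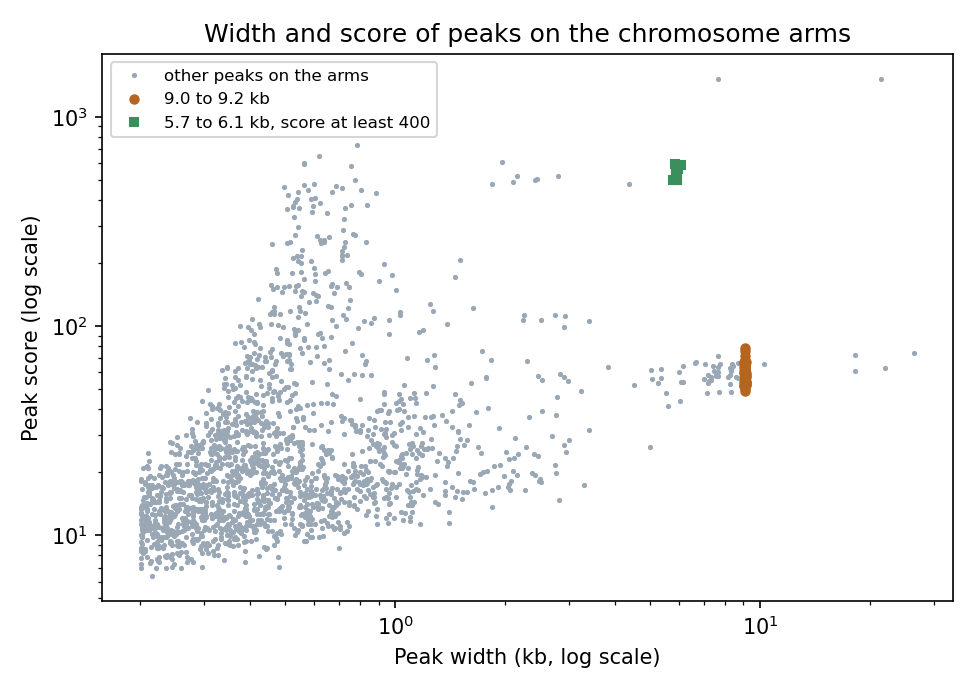
Width in kb against score, both on log axes, for the 1980 peaks on the chromosome arms, each point being a peak. Points below 1 kb rise steeply to a score of 736, the peaks of 9.0 to 9.2 kb form a column between 49.1 and 78.3, and the 7 peaks of 5.7 to 6.1 kb with a score of at least 400 lie between 498 and 594.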

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

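All tests in this part were chosen after the result was seen. The mitochondrial genome, which was left out of the comparisons of arms and of Uextra with the arms, carried 19 peaks. This is more than the limit of 3 that a count of 0 allows, which does not say whether the number is unusual. Relative to its span of 0.0193 Mb, this was 983 peaks per Mb, against 359 on Uextra, the next densest group. The peaks covered 59.7% of its span, against 23.2% on Uextra, with a median score of 45.9. No test was run on this difference.

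The concentration of peaks on the centromere side, seen over the 5 large arms together, with no single arm past the test when all peaks are used and 2L alone past it at or above the median score of the arms (adjusted p = 0.026 by circular-shift permutation), is a pattern that a split of broad regions into adjacent peaks could produce. After peaks within 10 kb were merged, 16.9% of 937 regions on the large arms still lay in the centromere-side 10%, against 10.0% over circular shifts (p = 0.0004, n = 937 regions). Splitting within 10 kb is therefore not the whole cause, although the share fell from 25.5%. A lower quality of assembly near the centromeres and a preference of the precipitated protein for this chromatin both stay open. So do reads shared between repeat copies, since no sequence or mapping quality was at hand. No biological explanation was tested, since no value per library separates ChIP from input.

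The density of peaks on Uextra was 21.8 times that on the arms. Reads shared between repeat copies may raise both the count and the score there, and so would a true preference for sequence of this kind. Neither can be excluded, because no sequence, mapping quality or library value was at hand. The heterochromatin scaffolds, whose median score was 17.0 against 78.8 on Uextra, show that placement outside the arms did not by itself go with a high score.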

How the results depend on the processing

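The alternatives called added here were chosen after seeing the data, as were all those for Uextra and for the centromere side. No paired analysis was possible because the list has no column for any of the 6 libraries, so neither the replicate number nor leaving out a replicate could be tried. The alternatives for promoters, gene features, motifs, gene lists and genes per arm were not run, for want of a release 5 sequence and annotation. The rank correlation of width and score kept its direction and call under 7 alternatives, of which the log scale cannot move a rank and 5 were added. The excess score of Uextra did so after merging within 500 bp and for peaks of at most 1 kb. Merging within 10 kb gave 105, which says nothing on it, since a merged region takes its highest score and Uextra had more peaks per region. The share of peaks with a neighbour within 5 kb did so under 9 alternatives and fell to 0 for focal peaks (added), where 0.96% was the mean at random. Merging within 10 kb was not run for it, since that leaves no such neighbour by construction. The 9 alternatives therefore do not exclude that a split of broad regions into adjacent peaks gave part of this share. The median spacing lost its call at or above the list median, in the top 25% and for focal peaks. Of the 6 arms, 3 passed as deposited and 0 passed at or above the list median, in the top 25% and for focal peaks, where 328, 154 and 130 arm peaks were left. In those 3 settings the density of chromosome 4 was 0.30, 0.64 and 0.75 times expectation, that of X was 1.19, 1.25 and 1.20, and that of 3L was 0.91, 0.92 and 0.98. In the top 25%, 3R was at 1.01, and for focal peaks 2L was at 0.96. At or above the arms' median score (added), 3L was at 0.95 and X at 1.07. X was also at 1.07 when peaks within 10 kb were merged (added), 1.04 without the centromere-side 10% (added) and 1.03 by covered bases, by which chromosome 4 was at 1.55, and 3L was at 0.96 without the centromere-side 10%. None of these 3L and X values passed the test where one was run. The centromere-side share was 12.8% at or above the list median, 13.1% in the top 25% and 8.53% for focal peaks, none past the test, and it stayed past the test under 9 alternatives, leaving out each arm included. Uextra held 89.8% of peaks at or above the list median, 88.9% of the top 25%, 83.5% at or above the arms' median, 78.2% of peaks of at most 1 kb and 94.0% of focal peaks. Its 15.0% of regions merged within 10 kb follows from its dense peaks on joined scaffolds and says nothing on its share. At or above the arms' median score 3 arms still passed and the centromere-side share was 23.5%. The stricter sets hold fewer peaks, and beyond that the cause was not tested. Arm densities rest on spans between peaks, which most affects chromosome 4.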

Other observations

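The tests in this part were chosen after the data had been seen. A shared width recurred among the wide peaks on the arms. As many as 48 peaks were 9.0 to 9.2 kb wide, with a median of 9084 bp, and they covered 436 kb of the 2077 kb covered on the arms. Of these, 15 were on 3L, 11 on 3R, 8 on 2L, 8 on 2R and 6 on X, and 2 more peaks of this width were on the heterochromatin scaffolds, 0 on U and 0 on Uextra. No arm passed the exact binomial test against an even spread (adjusted p between 0.437 and 1). Their scores lay between 49.1 and 78.3, with a median of 58.3.

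Another set of wide peaks had far higher scores, and was picked by eye from a plot of width and score. The 9 peaks between 5.7 and 6.1 kb with a score of at least 400 lay on 2L, 2R, 3R, X, 2RHet and 3RHet and scored 498 to 611. Each had a neighbouring peak of 496 to 568 bp, with a score of 299 to 460, at a gap of 56 to 308 bp (8 of the 9 within 300 bp, the limit first used). The neighbour was on the low-coordinate side in 5 cases and on the high-coordinate side in 4. Measured from end to end, each such couple spanned 6521 to 6631 bp. On 2L, for example, the wide peak ran from 21691782 to 21697697 and its neighbour from 21697873 to 21698398. On 3R, in the other order, the neighbour ran from 16092180 to 16092685 and the wide peak from 16092850 to 16098798.

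A smooth spread of widths does not account for the 9.0 to 9.2 kb peaks. The fullest 200 bp window began at 8967 bp, and so overlaps the 9.0 to 9.2 kb group of 48 peaks without being the same. It held 52 peaks, against a mean of 11.1 and at most 20 over 10000 smoothed resamples (p = 0.0001, the smallest they can give, n = 120 peaks). Without the 9.0 to 9.2 kb peaks the fullest window began at 5884 bp, inside the width range of the 5.7 to 6.1 kb set. It held 8 peaks of any score, against a mean of 7.05 over the smoothed resamples (p = 0.306, n = 72 peaks). This scan took arm widths alone, without scores, neighbours, end-to-end lengths or the heterochromatin scaffolds. It therefore does not test the set of 5.7 to 6.1 kb peaks, whose widths of 5755 to 6058 bp also exceed a 200 bp window. Full-length copies of 1 repeat family that share reads are a candidate explanation for the 9.0 to 9.2 kb peaks, since they would have equal lengths and could occur on every large arm. The relative interquartile range of their scores was 0.72 times that of the other 67 peaks of at least 4 kb (95% bootstrap interval 0.28 to 1.07). The interval includes 1, and the ratio could differ between a p and a q. It therefore does not decide the explanation, which stays open. The reference annotation of transposable elements in release 5, not used here, would bear on it, and a count of ChIP and input reads over these copies would show whether the enrichment is of the protein or of the repeat.

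Of the 130 focal peaks on the arms, 117 had no other peak within 400 bp, and 13 (10.0%) had one, compared with 951 of all 1980 arm peaks (48.0%). At a limit of 300 bp the shares were 9.23% and 42.4%. Of the 13 focal peaks with a peak within 400 bp, 7 were narrow neighbours of the 5.7 to 6.1 kb peaks described above. The focal peaks and those couples are therefore not separate sets. Of the 129 focal peaks on the large arms, 8.53% lay in the centromere-side 10%, against 25.5% of all peaks on the large arms. Neither difference was tested. Whether this set carries the motif of Tango dimers or that of TCF, named in the antibody label and in the title, was not analysed here.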
